A study of Mus musculus with 8 samples.

How the data were processed

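RNA from whole pancreas of mice aged 3 weeks was measured on 8 Affymetrix expression arrays, 2 for each of 4 groups. The labels gave the groups NOD and NOD.scid, each without and with the BDC2.5 transgene. Per the labels' protocols, tissue was homogenised in guanidine isothiocyanate, RNA was isolated 2 times from 6 animals each and pooled, and about 10 ug of total RNA was labelled. Whether the 2 arrays of a group came from separate pools is not given in the sources used here. The p-values therefore measure only the spread between these arrays, which may be technical.

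The deposited table held 12488 probe sets per array, with values on a log scale taken to be log2. The authors' normalization, background correction and summary of probes are not given in the sources used here. The base was inferred from the values, which reached at most 13.78; a natural or decimal logarithm of that size would exceed what a scanner records. The array medians lay between 4.24 and 4.30, so the log2 values were used as deposited with no further scaling. Of the probe sets, 66 were array controls and 12422 were tested. The platform annotation gave 1 gene symbol for 10833 of the tested probe sets, several for 396 and none for 1193. Symbols were checked through gene identifiers against the GRCm38.p6 annotation, where 10817 matched and 0 changed. That annotation was used only for names and for which genes neighbour each other. No genome build was named with these values, so no coordinates are given. A gene was represented by its probe set with the highest mean over the 8 arrays, which gave 8251 genes. Of these, 2073 had more than 1 probe set, and probe sets that did not pass or went the other way are given for the genes named by fold change.

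Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, because 2 arrays per group leave too few degrees of freedom alone. The fit had 4 residual degrees of freedom and a prior worth 8.07. Moderated, two-sided tests with a variance trend were adjusted by the Benjamini-Hochberg method over the 12422 probe sets, with a threshold of 0.05. Fold changes are differences of mean log2 values with their standard error (SE). The 5 comparisons were the transgene within NOD.scid, the transgene within NOD, scid without the transgene, scid with the transgene, and the interaction, which is the difference between the 2 transgene effects. The number of arrays limits the precision of every value.

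Before the data were examined, 33 lists of genes were fixed for cell types and processes, with 590 of their 757 entries measured. Each list with at least 5 measured genes was tested with limma's camera at a preset correlation between genes of 0.01, and p-values were adjusted over the lists within a comparison. With a correlation estimated from the residuals, 4 of the 47 list calls held. These were the lists for MHC class II, interferon gamma response and MHC class I, erythrocyte, and proliferation with the transgene in NOD.scid. For a list, the count of genes past the threshold over all probe sets is given beside the count adjusted over the list alone. Other set tests were run with fry, whose p-value asks whether a list's genes move one way on balance.

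Genes were named by a rule fixed at the same time. For each pairwise comparison it took up to 12 genes per direction with the largest fold change past the threshold. Both arrays of the higher group had to lie above both of the lower, the higher mean had to exceed the median of all probe sets (4.27), and the probe set had to carry exactly 1 symbol. The interaction gave 5 genes per direction. Up to 4 members with the smallest p were taken for each described list, and some genes were always reported. Of the latter, Ins1, Igkc and Trbc1 had no probe set of a single symbol and were not analysed here by name.

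The test was tried on simulated data before use. In 5 simulations of the comparison of BDC2.5/NOD.scid with NOD.scid over 12422 probe sets, 200 were changed, 50 at each size. The fit recovered 77.6% of those changed by 0.5 on the log2 scale and 100% of those changed by 1, 2 or 3. False calls made up 6.26% of all calls. The simulated noise was normal and independent between probe sets and arrays, with the fitted spread. Correlated genes and differences between arrays were not simulated, so these rates may be better than those in the data. Alternatives fixed before the data were examined covered quantile normalization, centring of array medians, a filter on dim probe sets, the variance prior, the arrays in the fit, a term for the title number, array weights, the threshold, and each array left out in turn. Others were added after seeing the data: a term for the level of the actin control, the BDC2.5/NOD arrays counted as 1 sample, and the arrays of high actin control left out. Floors on linear values did not apply to log2 values. Tables were handled with pandas 2.3.3 and plots with matplotlib 3.10.9.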

Results

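Gene expression was measured in whole pancreas of mice aged 3 weeks on 8 arrays, with 2 arrays in each of 4 groups. NOD is an inbred mouse strain that develops autoimmune diabetes. NOD.scid carries the scid mutation of Prkdc, a gene needed to join the segments of antigen receptor genes, and lacks mature T and B lymphocytes. BDC2.5/NOD carries the rearranged T cell receptor of a diabetogenic CD4 T cell clone that recognises an islet antigen. BDC2.5/NOD.scid combines both, so that the transgenic receptor is formed without other lymphocyte receptors. The design asks what the transgenic T cells change in the pancreas, and whether this depends on the other lymphocytes. All groups are named as labelled.

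The deposited log2 values of the 2 arrays of a group correlated across probe sets at Pearson r from 0.9912 in NOD.scid to 0.9961 in BDC2.5/NOD. Arrays of different groups correlated at 0.9773 to 0.9902. The first principal component held 36.9% of the variance and parted the arrays with the transgene, at -13.9 to -10.7, from those without it, at 9.83 to 14.7. The second component held 25.3% and parted BDC2.5/NOD from BDC2.5/NOD.scid. Arrays also differed in a way the groups do not explain. The middle beta-actin control probe set read 9.26 to 9.55 on NOD replicate 1, NOD.scid replicate 1 and BDC2.5/NOD.scid replicate 2, and 6.95 to 7.74 on the other 5. The 3' to 5' ratio of actin was 3.94 to 4.90 on the former and 3.15 to 3.53 on the latter. That of Gapdh was 2.43 on NOD replicate 1 and 1.66 to 1.86 elsewhere. The BDC2.5/NOD pair stood apart in 2 ways. Its SD within the pair was 0.094, against 0.131 to 0.143 in the other groups, and its mean BioB hybridization control was 7.02 and 7.06, against 5.89 to 6.44. Whether the BDC2.5/NOD arrays were prepared apart is not known. Any such difference cannot be separated from the transgene in NOD, scid with the transgene or the interaction, which all use this pair. Xist, transcribed from the inactive X chromosome of females, read 7.26 and 4.60 in NOD, 4.19 and 5.92 in BDC2.5/NOD.scid and 3.35 to 3.71 on the other arrays.

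Prkdc lay near background in every group, at 3.60 ± 0.15 (SD, n = 2) in NOD, 3.60 ± 0.08 in NOD.scid, 3.45 ± 0.12 in BDC2.5/NOD and 3.44 ± 0.06 in BDC2.5/NOD.scid. The scid allele is a point mutation, so this level does not check the labels. The deposited values carry no detection calls. Of the genes named below, Cxcl9, Saa3, Gzmb, Chgb, Hemgn, Tnfrsf1b, F2, Xist and Eif2s3y read 3.60 or less in the dimmer group of a comparison. The level of background was not measured, so their fold changes there may understate the size of the difference. H2-Ea, which NOD mice do not express, was at 3.40 to 3.48 in all groups. The T cell genes Cd3e, at 5.64 to 5.87, and Cd3g, at 3.44 to 3.51, passed in no comparison. The probe set for kappa light chain constant and variable genes read 7.35 in NOD, 5.33 in NOD.scid, 5.64 in BDC2.5/NOD and 6.35 in BDC2.5/NOD.scid. The last value is above that of NOD.scid, which the scid label does not lead one to anticipate.

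With the transgene in NOD.scid mice, genes of the Reg family, of antigen presentation and of macrophages were higher, while islet hormone, red cell and neutrophil genes were lower. With an estimated correlation the antigen presentation and red cell lists held, and those for the Reg family, macrophages and neutrophils (adjusted p = 0.094 for each) and for islet hormones (adjusted p = 0.257) did not. Reg3g and Reg3b, secreted lectins made by stressed acinar cells, had log2 fold changes of 4.74 (SE 0.119, 26.7-fold) and 3.80 (SE 0.075, 13.9-fold). H2-Aa, a chain of MHC class II, rose by 2.96 and B2m, the light chain of MHC class I, by 2.84. Ins2, which encodes insulin, fell by 1.45 (SE 0.087) and Sst, which encodes somatostatin, fell by 1.39. In all, 295 probe sets were higher and 500 lower in BDC2.5/NOD.scid than in NOD.scid.

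Of the Reg family and injury list, 7 of 15 measured genes rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 3.59e-09, and adjusted p = 0.094 with an estimated correlation). Besides Reg3g and Reg3b, Reg3a rose by 2.78 (limma adjusted p = 3.85e-09) and Reg2 by 2.53, while a dim second probe set of Reg2 was at 0.14 and did not pass. Reg1 was at 12.73 ± 0.13 (SD, n = 2) in NOD.scid and 12.66 ± 0.12 in BDC2.5/NOD.scid and did not pass. In the list for interferon gamma response and MHC class I, 15 of 28 genes rose and 1 fell, or 18 and 2 adjusted over the list alone (camera adjusted p = 7.26e-17, and adjusted p = 0.0427 with an estimated correlation). H2-K1 and H2-D1, class I heavy chains, rose by 2.40 (1.59 on a second probe set, and 0.01 and not past the threshold on another) and 2.39, and Psmb8, an immunoproteasome subunit, by 1.43. The MHC class II list had 5 of 11 genes up, 6 adjusted over the list alone (camera adjusted p = 4.72e-10, and adjusted p = 0.0427 with an estimated correlation). Cd74, the invariant chain, rose by 2.73 (SE 0.233), H2-Eb1 by 2.03 and H2-Ab1 by 1.81. Of 26 macrophage and monocyte genes, 11 rose, 17 adjusted over the list alone (camera adjusted p = 2.93e-14, and adjusted p = 0.094 with an estimated correlation). Ctss, the protease that trims the invariant chain, rose by 2.61, Lyz2 (lysozyme) by 1.95, Cd14 by 1.13 and C1qc by 1.08.

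Lrg1, Saa3 and several chemokine genes rose in the same comparison. Lrg1, a leucine-rich glycoprotein induced in inflammation, had a log2 fold change of 3.63 (SE 0.102). Saa3, a serum amyloid A protein near background in NOD.scid (3.54), had one of 2.75 (SE 0.115), which may understate the difference. Of 32 chemokine, cytokine and adhesion genes, 5 rose, and 5 adjusted over the list alone (camera adjusted p = 5.77e-05, and adjusted p = 0.0899 with an estimated correlation). Among them were Ccl9 (1.34), Ccl8 (1.21), Cxcl9 (0.90) and Ccl5 (0.66). Of 25 genes for apoptosis and NF-kB targets, 3 rose, 4 adjusted over the list alone (camera adjusted p = 6.13e-05, and adjusted p = 0.094 with an estimated correlation), with Nfkbia at 0.84, Gadd45b at 0.56 and Tnfrsf1b at 0.51. Of 26 immediate early and heat shock genes, 4 rose, or 6 with 1 lower adjusted over the list alone (camera adjusted p = 0.00252, and adjusted p = 0.094 with an estimated correlation), namely Dusp1, Zfp36, Klf6 and Btg2. The metallothioneins Mt1 and Mt2 rose by 1.53 and 1.42. T cell genes moved little. No member of 20 passed, although the list as a whole shifted upward (camera adjusted p = 0.0465, and adjusted p = 0.37 with an estimated correlation). Of 29 T cell activation genes, Ccl5 and Gzmb, a cytotoxic granule protease at 0.46, rose (camera adjusted p = 0.0373, and adjusted p = 0.37 with an estimated correlation). Both T cell calls were lost without NOD.scid replicate 1 and without BDC2.5/NOD.scid replicate 2, and fry made neither (adjusted p = 0.0816 and 0.089). The T cell list also lost its call without BDC2.5/NOD.scid replicate 1, without either BDC2.5/NOD array and with the actin control as a term (camera adjusted p = 0.0529). The activation list lost its call under quantile normalization (camera adjusted p = 0.0601). Of 5 probe sets annotated to the T cell receptor segments Trav9d-3 and Trbv1, 3 rose, at 0.49 and 0.83 for Trav9d-3 and 0.58 for Trbv1, and the others, at 0.25 and 0.04, did not pass.

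Of the islet genes, some hormones fell. Iapp, co-secreted with insulin, had a log2 fold change of -1.37 (SE 0.149) and Gcg, which encodes glucagon, one of -1.16 (SE 0.138). Sst and Gcg were the 2 of 7 genes down in the list of other islet hormones, and Ins2 and Iapp the 2 of 15 in the beta cell list, with the same counts adjusted over the list alone. The camera adjusted p was 0.0265 for the former and 0.0318 for the latter, and adjusted p = 0.257 for both with an estimated correlation. The former call was lost without BDC2.5/NOD.scid replicate 2 (adjusted p = 0.0937) and the latter without NOD.scid replicate 2 (adjusted p = 0.113). Of 20 secretory granule genes, 5 fell, 7 adjusted over the list alone, led by Scg2 at -0.81, Chgb at -0.81 and Cpe at -0.70 (camera adjusted p = 0.00403, and adjusted p = 0.195 with an estimated correlation). Without BDC2.5/NOD.scid replicate 1 that adjusted p was 0.0559.

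Some genes of other cells fell as well. Of 7 erythrocyte genes, 5 fell, 6 adjusted over the list alone (camera adjusted p = 4.68e-08, and adjusted p = 0.0427 with an estimated correlation), with Hbb-b2 at -1.43 and Hba-a1 at -1.16. Hemgn, a nuclear protein of erythroid precursors, fell by 1.80, to near background (2.67), and Prdx2, an antioxidant enzyme abundant in red cells, was at -1.36. Of 16 neutrophil genes, 5 fell, and 5 adjusted over the list alone (camera adjusted p = 0.00013, and adjusted p = 0.094 with an estimated correlation), with S100a8 at -2.39, S100a9 at -2.02, Camp at -1.28 and Ngp at -0.94. Of 29 proliferation genes, 11 fell, 14 adjusted over the list alone (camera adjusted p = 8.72e-07, and adjusted p = 0.0427 with an estimated correlation). Pcna, the clamp of DNA polymerase, fell by 1.04, Cdc20 by 0.76 and Cdk1 by 0.61. Car2, carbonic anhydrase of ducts and red cells, fell by 2.64, and 4 of 17 duct genes were down, with 6 down and 1 up adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.244 with an estimated correlation). Of 19 developmental regulators, 5 fell, 6 adjusted over the list alone, with Cdkn1c at -0.84, Foxa2 at -0.66 and Dlk1 at -0.47 (camera adjusted p = 0.04, and adjusted p = 0.257 with an estimated correlation). These 2 list calls were each lost without BDC2.5/NOD.scid replicate 1 (adjusted p = 0.0804 and 0.272). The former was also lost without NOD.scid replicate 1 (0.17) and the latter without NOD.scid replicate 2 (0.0783). The red cell, neutrophil and Car2 values rest on high levels in NOD.scid, which are described with the comparison of NOD.scid and NOD. Some of these genes had a further probe set that did not pass, with -0.38 for Hemgn, -0.12 for Mgst3, -0.04 for Pip4k2c and up to 0.15 for Prdx2. Mgst3 (-1.57) and Pip4k2c (-1.25) fell too, while a probe set annotated to Wdr92 was 3.61 higher (limma adjusted p = 3.57e-08). For these and for Prdx2, NOD.scid alone stood apart. It was at 5.82 for Mgst3 (4.25 to 4.67 in the other groups) and 6.28 for Pip4k2c (4.66 to 5.11). For Prdx2 it was at 7.86 (6.5 to 6.9) and for Wdr92 at 8.29 (11.25 to 11.9).

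The count of 795 was 445 without BDC2.5/NOD.scid replicate 2, with 234 higher and 211 lower, so the excess of lower calls rested on that array. It was 521 without NOD.scid replicate 1. With the actin control split as a term it was 1315. The median of the interferon gamma list was 0.417 pooled, 0.438 within the low and 0.405 within the high arrays. For macrophage genes these were 0.320, 0.358 and 0.307, and for erythrocyte genes -0.668, -0.674 and -0.871.

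**Figure D1:**
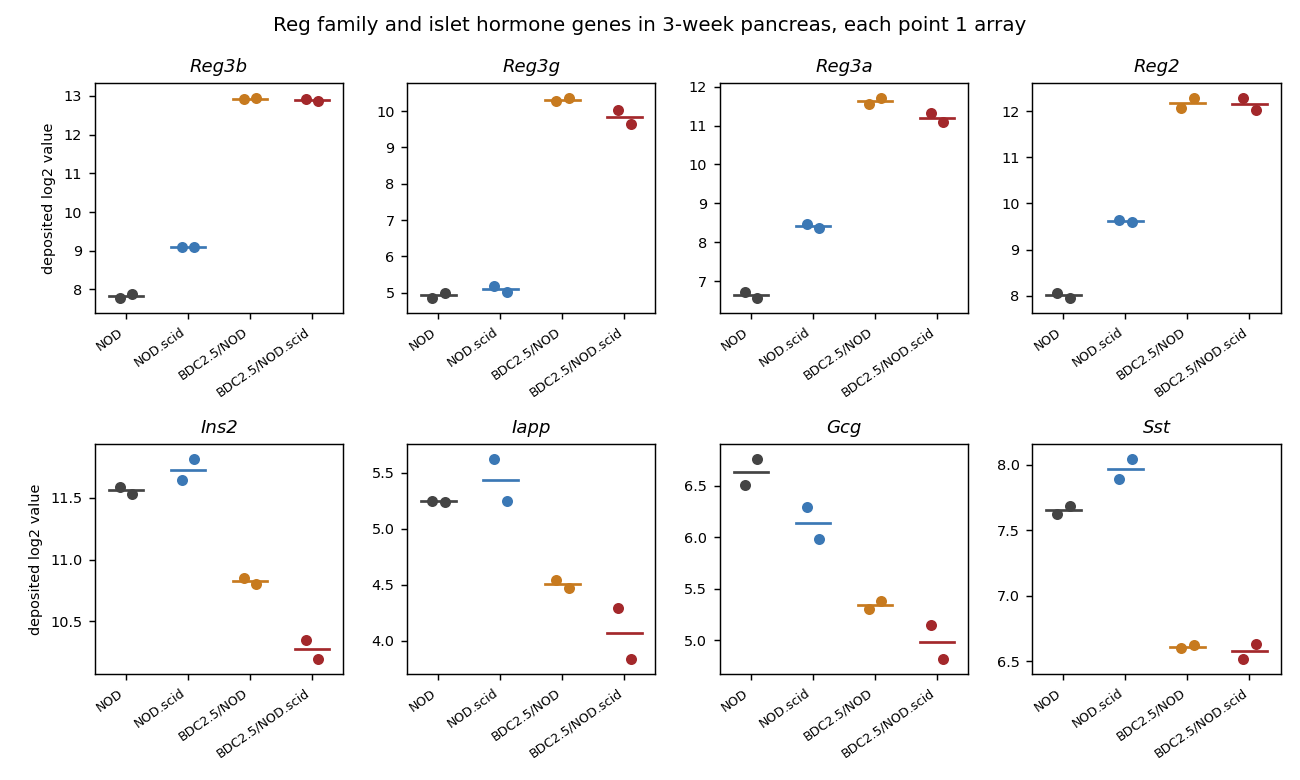
Deposited log2 values (vertical axis) of 4 Reg family genes and 4 islet hormone genes in the 4 groups (horizontal axis), where each point is 1 array and each line a group mean of 2 arrays. Reg3b was near 12.9 on the 4 arrays with the transgene, 9.09 in NOD.scid and 7.83 in NOD, while Ins2 was at 11.56 and 11.73 without the transgene and at 10.82 and 10.27 with it.

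With the transgene in NOD mice, 4 members of the Reg family rose further than any other named gene, and genes for protein folding in the endoplasmic reticulum rose with it, while genes of extracellular matrix and ribosomes fell. With an estimated correlation none of these list calls held (adjusted p = 0.396 for the Reg family, 0.253 for the unfolded protein response, and 0.246 for matrix and for ribosomes). Reg3g, Reg3b and Reg3a had log2 fold changes of 5.38 (SE 0.119, 41.6-fold), 5.10 (SE 0.075, 34.3-fold) and 4.98 (SE 0.097, 31.6-fold). Hspa5, the chaperone BiP, rose by 1.53 (SE 0.124). Cpt1a, which carries fatty acids into mitochondria, fell by 1.59 (SE 0.113). In all, 486 probe sets were higher and 504 lower in BDC2.5/NOD than in NOD.

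In the Reg family and injury list, 4 of 15 genes rose and 3 fell, and the counts adjusted over the list alone were the same (camera adjusted p = 0.00576, and adjusted p = 0.396 with an estimated correlation). Reg2 rose by 4.17 (limma adjusted p = 5.38e-11), while the probe sets of Reg1, at 0.08 and 0.26, did not pass. Mt1 and Mt2, metallothioneins that also stand in this list, fell by 0.58 and 0.41. Of 24 genes of the unfolded protein response, 12 rose, 15 adjusted over the list alone (camera adjusted p = 6.33e-09, and adjusted p = 0.253 with an estimated correlation). The largest were Creld2 at 2.08, Pdia4, a disulfide isomerase, at 1.82 and Hsp90b1, an endoplasmic reticulum chaperone, at 1.07. Among cytosolic chaperones, Hsph1 rose by 1.52 and Hspa8 by 0.73. Itih4, an acute-phase protein, rose by 3.06, 1810009J06Rik by 2.82 and F2, which encodes prothrombin, by 1.21. Among acinar genes 3 of 21 rose and 3 fell, 4 and 4 adjusted over the list alone, and the list as a whole did not shift (camera adjusted p = 0.945). Pla2g1b, the pancreatic phospholipase, rose by 1.52, Sycn, a zymogen granule protein, by 0.95 and Amy1 (amylase) by 0.67, and Pnliprp1 fell by 0.53.

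The matrix list had 10 of 28 genes down, and 10 adjusted over the list alone (camera adjusted p = 1.13e-06, and adjusted p = 0.246 with an estimated correlation). Dcn (decorin) was at -1.45, Postn (periostin) at -1.38, Col1a2 at -0.77 and Col3a1 at -0.69. Of 14 ribosomal protein genes, 7 fell, 9 adjusted over the list alone, by about 0.6 for Rpl7, Rps7 and Rps4x (camera adjusted p = 1.13e-06, and adjusted p = 0.246 with an estimated correlation). Of 23 oxidative stress and detoxification genes, 3 fell, 5 adjusted over the list alone (camera adjusted p = 0.00576, and adjusted p = 0.246 with an estimated correlation), namely Mt1, Mt2 and Gstm1 (-0.57). Without NOD replicate 1 this list had an adjusted p of 0.0514. Of 29 proliferation genes, Mcm5 alone fell, at -0.34, and none passed adjusted over the list alone (camera adjusted p = 0.0136, and adjusted p = 0.246 with an estimated correlation). Outside these lists, Acaa2, a thiolase of fatty acid oxidation, was at -1.65, Txnip, a glucose-responsive inhibitor of thioredoxin, at -1.49, and Vtn (vitronectin) at -1.51. Further genes down were H2az2, Marcks, Ifrd1, Ly6e and Itm2a, at -1.73 to -1.58. Dimmer probe sets of Ly6e (-0.03) and Txnip (-0.18) did not pass.

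Islet hormones fell here too, with Gcg at -1.29, Sst at -1.04, Iapp at -0.74 and Ins2 at -0.73 (limma adjusted p = 0.000148, 2.21e-05, 0.00961 and 0.000297). As lists, the beta cell genes (3 of 15 down) and the other islet hormones (2 of 7 down, 1 up) did not pass, with camera adjusted p of 0.43 and 0.0783. With the actin control split as a term the latter passed (0.0397). Adjusted over the list alone, 3 beta cell genes were up and 3 down, and 2 other islet hormones were down and 1 up. Immune lists moved little. Of 28 interferon gamma and class I genes, 5 rose and 1 fell, 6 and 2 adjusted over the list alone, with H2-K1 at 0.66 and H2-D1 at 0.62, and the list did not pass (camera adjusted p = 0.0646, but 0.0337 with the actin control split as a term). No MHC class II gene of 11 and no macrophage gene of 26 passed, either over all probe sets or adjusted over the list alone, with camera adjusted p of 0.199 and 0.945. Ifitm3, an interferon-induced membrane protein, rose by 1.01 and Ifi27 by 0.76. Igkv6-23, a kappa variable segment, was at -1.72. Pdxdc1 had probe sets that disagreed, from -0.91 to 2.14, with 2 of 3 past the threshold in opposite directions.

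The count of 990 was 279 and 323 when BDC2.5/NOD replicate 1 or 2 was left out, and 479 without NOD replicate 1. When the 2 BDC2.5/NOD arrays were counted as 1 sample it was 278, and with the actin control split as a term 1507. Both BDC2.5/NOD arrays had a low actin control, so only the arrays of low actin control hold the comparison. Within these the median of the unfolded protein response list was 0.365, against 0.431 pooled. Centring array medians changed the split from 486 higher and 504 lower to 408 and 640.

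The 2 transgene comparisons share no array. Of the probe sets called, 64 were higher in both, against 11.5 anticipated for independent lists, and 135 were lower in both, against 20.3 (Fisher's exact test, two-sided, p = 2.51e-30 and 1.66e-76). A further 37 were called in opposite directions, against 31.5. Across probe sets, which are not independent replicates, the fold changes correlated at Pearson r = 0.339 and Spearman rho = 0.212. Reg3b, Reg3g, Reg3a and Reg2 were higher, and Ins2, Iapp, Gcg and Sst lower, in both.

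Between NOD.scid and NOD without the transgene, genes of red cells and neutrophils were higher in NOD.scid, as were members of the Reg family, while 4 of 24 genes of the unfolded protein response and 3 of 15 of adipocytes were lower. None of these list calls held with an estimated correlation (adjusted p = 0.0518 for red cell, 0.0756 for neutrophil, 0.469 for unfolded protein response and 0.211 for adipocyte genes), and fry did not call the unfolded protein response list (adjusted p = 0.136). S100a8 and S100a9, the subunits of calprotectin in neutrophils, had log2 fold changes of 2.10 (SE 0.202) and 1.81 (SE 0.108). Hemgn was higher by 1.99 (SE 0.113), from near background in NOD (2.48), and Hba-a1, a globin gene, by 1.03 (SE 0.084). Reg3a rose by 1.77 (SE 0.097, 3.42-fold). Scd1, a fatty acid desaturase, fell by 1.14 (SE 0.092) on its brightest probe set, with the dimmest of 3 at 0.10. In all, 92 probe sets were higher and 200 lower in NOD.scid.

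Of 7 erythrocyte genes, 5 rose, 6 adjusted over the list alone (camera adjusted p = 6.09e-12, and adjusted p = 0.0518 with an estimated correlation), including Hbb-b2 at 1.22, Slc4a1, the red cell anion exchanger, at 1.08 and Car1 at 0.89. The list's median was 0.889 pooled, 0.950 within the arrays of low actin control and 0.828 within those of high. Of 16 neutrophil genes, 6 rose, 8 adjusted over the list alone (camera adjusted p = 5e-10, and adjusted p = 0.0756 with an estimated correlation), including Camp, an antimicrobial peptide, at 1.25 and Ngp at 0.87. Its median was 0.243 pooled, and 0.320 and 0.247 within the low and high arrays. Proliferation genes shifted upward as a list of 29 without any gene past the threshold, or with 3 adjusted over the list alone (camera adjusted p = 0.000788, and adjusted p = 0.122 with an estimated correlation). Car2 rose by 2.63, Prdx2 by 0.96 and Pip4k2c by 1.17. Group means of Car2 were 6.77 ± 0.11 (SD, n = 2) in NOD.scid, 4.14 ± 0.06 in NOD, 3.67 ± 0.14 in BDC2.5/NOD and 4.13 ± 0.06 in BDC2.5/NOD.scid, so its level stood out in NOD.scid. Hemgn was also highest in NOD.scid, at 4.47 against 2.48 to 2.67 elsewhere. Dimmer probe sets of Hemgn (0.36) and Pip4k2c (0.04) did not pass.

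Reg2 rose by 1.62 (0.06 and not past the threshold on its dim probe set) and Reg3b by 1.26, and Tff1, a secreted trefoil peptide, by 1.26. The probe sets of Reg3g, at 0.17 and 0.13, and of Reg1, at 0.04 and 0.12, did not pass. The Reg family and injury list as a whole, with 3 of 15 up and 2 down, or 3 and 3 adjusted over the list alone, did not pass (camera adjusted p = 0.231). Of 18 type I interferon response genes, 3 rose, and 3 adjusted over the list alone (camera adjusted p = 0.0034, and adjusted p = 0.469 with an estimated correlation), namely Ifi27 at 0.82, Ifitm3 at 0.68 and Rsad2 at 0.57. Islet hormones did not pass, with Ins2 at 0.17, Iapp at 0.19, Sst at 0.31 and Gcg at -0.49.

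Among lower genes, Herpud1, part of the endoplasmic reticulum degradation machinery, was at -1.08 and Hsp90b1 at -0.83. Of 24 unfolded protein response genes, 4 fell, or 8 with 1 up adjusted over the list alone (camera adjusted p = 0.00187, and adjusted p = 0.469 with an estimated correlation). Of 15 adipocyte genes, 3 fell, 4 adjusted over the list alone (camera adjusted p = 0.00688, and adjusted p = 0.211 with an estimated correlation). Besides Scd1 these were Adipoq (adiponectin) at -0.98 and Car3 at -0.94. Of 21 acinar genes, Cuzd1 (-0.71) and Pnliprp2 (-0.47) fell, and 6 adjusted over the list alone (camera adjusted p = 0.0235, and adjusted p = 0.469 with an estimated correlation). Without NOD.scid replicate 2 or NOD replicate 1 the acinar list had an adjusted p of 0.087 and 0.215. Igkv6-23 was at -2.21 and the probe set for several kappa genes at -2.02, while of 22 B cell and immunoglobulin genes none passed, over all probe sets or adjusted over the list alone (camera adjusted p = 0.882). Erdr1 fell by 1.70, Sgk1, a kinase induced by glucocorticoids, by 1.44, Sesn1, a stress-induced regulator of growth signalling, by 1.36, and Adk, Nucb2 and Hspa9 by 1.10 to 0.97. Further probe sets of Erdr1 (-0.18) and Adk (-0.13 and -0.01) did not pass. The probe set annotated to Wdr92 was at -2.96 and that of Pdxdc1 at 2.31, with the other 2 Pdxdc1 probe sets lower, at -0.63 and near -1.

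The count of 292 was lower by over 1.5 times without 5 of the arrays: 159 without either BDC2.5/NOD array, 97 without NOD.scid replicate 2 (45 higher and 52 lower), 128 without NOD replicate 1 and 71 without NOD replicate 2. It was 143 with only the arrays of this comparison in the fit, and 739 with the actin control split as a term. Pip4k2c lost its call without NOD.scid replicate 1 (adjusted p = 0.0535), without NOD replicate 1 (0.0965), without NOD replicate 2 (0.061) and with a robust variance prior (0.0882). Car3 and Nucb2 lost theirs without NOD.scid replicate 2 (0.0883 and 0.0887) and without NOD replicate 2 (both 0.0909), and Adipoq without NOD replicate 2 (0.061).

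**Figure D2:**
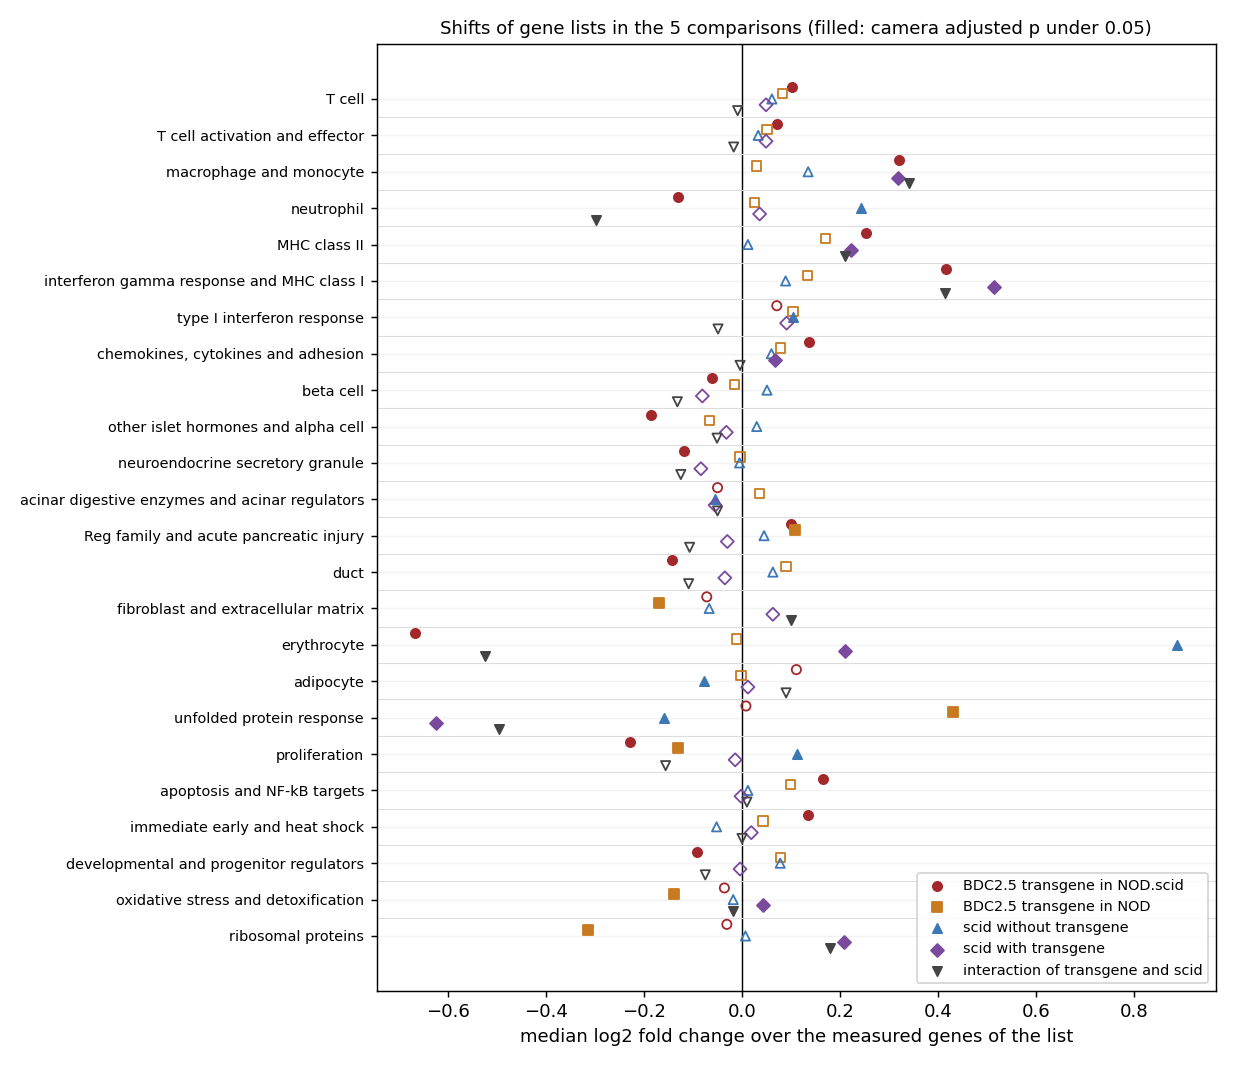
Median log2 fold change over the measured genes of each list (horizontal axis) for the lists called in at least 1 of the 5 comparisons (vertical axis), with a symbol for each comparison, filled where camera's adjusted p was under 0.05. The interferon gamma list stood at 0.417 and 0.514 in the comparisons of BDC2.5/NOD.scid with NOD.scid and with BDC2.5/NOD, and the erythrocyte list at 0.889 between NOD.scid and NOD.

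Between BDC2.5/NOD.scid and BDC2.5/NOD, which both carry the transgene, MHC and macrophage genes were higher in BDC2.5/NOD.scid and genes of the unfolded protein response were lower. With an estimated correlation none of these list calls held (adjusted p = 0.0785 and 0.133 for class I and II, and 0.159 for macrophages and for the unfolded protein response). B2m had a log2 fold change of 2.83 (SE 0.0996, 7.12-fold), H2-Aa one of 2.73 (SE 0.121) and Ctss one of 2.72 (SE 0.101). Txnip rose by 2.72 (0.35 and not past the threshold on a dimmer probe set) and Pdk4, a kinase that restrains pyruvate oxidation, by 2.53. Creld2 fell by 1.85 (SE 0.104) and Pdia4 by 1.68. The Reg genes differed little, with Reg3b at -0.04, Reg2 at -0.03 (-0.55 and past the threshold on its dim probe set), Reg3a at -0.42 and Reg3g at -0.47, of which the last 2 passed. In all, 372 probe sets were higher and 665 lower in BDC2.5/NOD.scid.

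Of 28 interferon gamma and class I genes, 17 rose and 1 fell, 17 and 2 adjusted over the list alone (camera adjusted p = 1.34e-13, and adjusted p = 0.0785 with an estimated correlation), with H2-D1 at 1.86, H2-K1 at 1.78 and Psmb9 at 1.22. Of 11 MHC class II genes, 5 rose, and 5 adjusted over the list alone (camera adjusted p = 4.86e-08, and adjusted p = 0.133 with an estimated correlation). These included Cd74 at 2.07 and H2-Ab1 at 1.58. Of 26 macrophage genes, 12 rose, 14 adjusted over the list alone (camera adjusted p = 8.49e-16, and adjusted p = 0.159 with an estimated correlation), with Lyz2 at 2.29 (0.33 and not past the threshold on a dim probe set), Cd14 at 1.24 and C1qa, a complement component made by macrophages, at 1.10. Lrg1 rose by 2.74 and Saa3 by 2.51. Of 32 chemokine and cytokine genes, 4 rose, and 4 adjusted over the list alone (camera adjusted p = 0.00299, and adjusted p = 0.161 with an estimated correlation), namely Ccl8, Ccl9, Cxcl9 and Ccl5, at 1.09 to 0.81. Jchain, which joins secreted immunoglobulins, rose by 0.46 and Igkv6-23 by 0.71, while the B cell list as a whole did not pass (camera adjusted p = 0.314), with 1 of 22 up, and 1 adjusted over the list alone.

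The unfolded protein response list had 15 of 24 genes down, 17 adjusted over the list alone (camera adjusted p = 1.2e-12, and adjusted p = 0.159 with an estimated correlation). Dnajb9 was at -1.53, Hsp90b1 at -1.35 and Hspa5 at -1.31, and Pdia3 and the cytosolic Hsph1 were at -1.71 and -1.93. Psat1, an enzyme of serine synthesis, fell by 1.14 and Rars, an aminoacyl-tRNA synthetase, by 1.19. Fasn (fatty acid synthase) fell by 1.21, and Scd1 was lower too. The acinar genes Sycn, Pla2g1b and Amy1 fell by 0.83, 0.79 and 0.71, as did Itih4 by 1.27 and 1810009J06Rik by 2.40. Ins2 fell by 0.55 (limma adjusted p = 0.00181) on its brighter probe set but was at 0.08 on the other, which did not pass, whereas Iapp (-0.43), Gcg (-0.36) and Sst (-0.03) did not pass. Of 23 oxidative stress genes, 4 rose and 1 fell, 6 and 3 adjusted over the list alone (camera adjusted p = 0.0263, and adjusted p = 0.182 with an estimated correlation), with Mt1 at 1.44 and Mt2 at 1.37. With the actin control split as a term this list had an adjusted p of 0.0546. Rps7 and Rps3 were the 2 of 14 ribosomal genes up, and 2 adjusted over the list alone (camera adjusted p = 4.78e-05, and adjusted p = 0.204 with an estimated correlation). Of 7 erythrocyte genes, Hba-a1 (0.51) and Hbb-b2 (0.41) rose, 3 adjusted over the list alone (camera adjusted p = 0.0031, and adjusted p = 0.159 with an estimated correlation). Errfi1, an inducible inhibitor of the epidermal growth factor receptor, rose by 1.93 and Dcn by 1.22.

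The count of 1037 was 370 and 329 when BDC2.5/NOD replicate 1 or 2 was left out, 635 without BDC2.5/NOD.scid replicate 2 (303 higher and 332 lower), 311 with the BDC2.5/NOD arrays counted as 1 sample and 1526 with the actin control split as a term. Within the arrays of low actin control, which alone hold both groups, the median was 0.529 for the interferon gamma list (0.514 pooled) and -0.499 for the unfolded protein response list (-0.625 pooled).

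**Figure D3:**
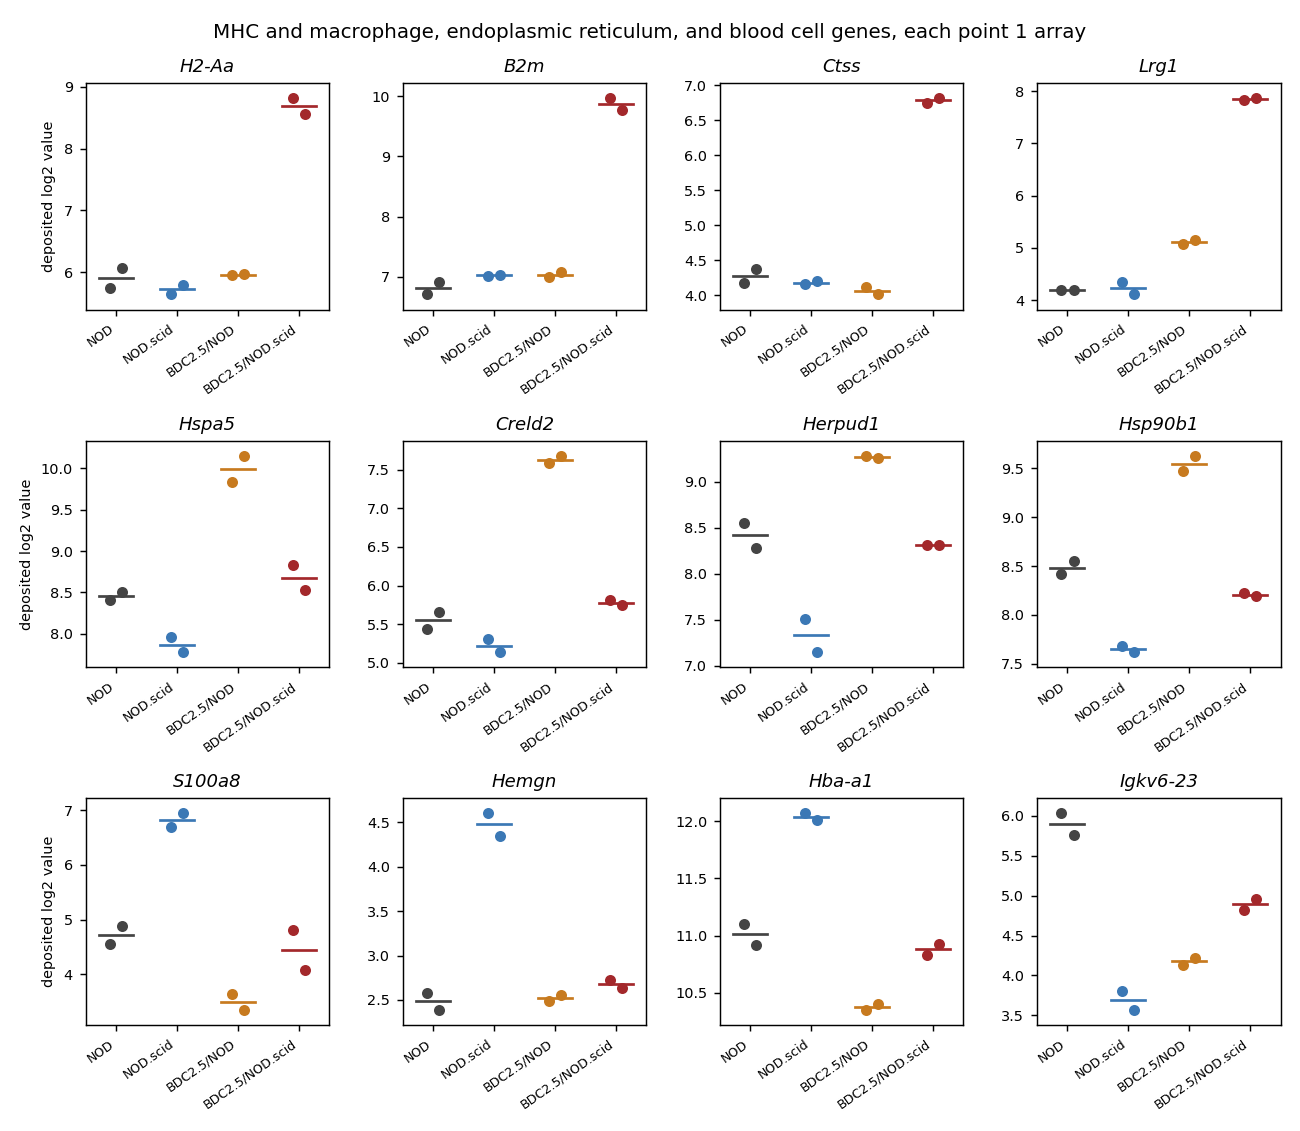
Deposited log2 values (vertical axis) of 12 genes in the 4 groups (horizontal axis), where each point is 1 array and each line a group mean of 2 arrays. B2m was at 9.87 in BDC2.5/NOD.scid and 6.82 to 7.04 elsewhere, Creld2 at 7.63 in BDC2.5/NOD and 5.23 to 5.78 elsewhere, and Hemgn at 4.47 in NOD.scid and 2.48 to 2.67 elsewhere.

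The 2 scid comparisons also share no array, and the same limit of a shared estimate of spread applies to their overlap. Of the called probe sets, 11 were higher in both, against 2.76 anticipated for independent lists, and 50 were lower in both, against 10.7 (Fisher's exact test, two-sided, p = 9.16e-05 and 1.1e-20). In opposite directions 30 were called, against 10.9, so the excess was not limited to agreement, and the fold changes correlated across probe sets at Pearson r = 0.0888 and Spearman rho = 0.0995. Herpud1, Hsp90b1, Hspa5 and Scd1 were lower with scid in both.

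The interaction tests whether the transgene effect differed between NOD.scid and NOD, and it did for genes of antigen presentation, macrophages, the unfolded protein response and blood cells, among 9 lists called. All 9 list calls were lost with an estimated correlation. H2-Aa had an interaction of 2.91 (SE 0.171) and B2m one of 2.62 (SE 0.141), since both rose in NOD.scid and neither passed in NOD (0.05 and 0.22). Txnip, at 3.06 (0.31 and not past the threshold on its dimmer probe set), and Pdk4, at 2.95, rose with the transgene in NOD.scid and fell in NOD, at 1.57 and 2.32 in the former and -1.49 and -0.63 in the latter. Reg3a, at -2.20, and Reg3b, at -1.31, rose on both backgrounds but by more in NOD, where they started lower. Without the transgene Reg3a read 6.65 in NOD and 8.42 in NOD.scid, and Reg3b 7.83 and 9.09. With it they differed less, at 11.63 in BDC2.5/NOD and 11.2 in BDC2.5/NOD.scid for Reg3a, and 12.93 and 12.88 for Reg3b. These Reg3b values lay near the array maxima of 13.66 to 13.78, and whether that limited its rise was not tested. Hspa5 and Herpud1 rose on both backgrounds, by 0.81 and 0.98 in NOD.scid. In all, 276 probe sets had a higher and 310 a lower effect in NOD.scid.

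By list, 11 of 28 interferon gamma and class I genes, 4 of 11 MHC class II genes and 8 of 26 macrophage genes had a higher effect in NOD.scid, or 15 (with 4 lower), 4 and 13 adjusted over the list alone. Their camera adjusted p was 6.61e-09, 5.28e-06 and 1.14e-09, and adjusted p = 0.147, 0.147 and 0.254 with an estimated correlation. Of 24 unfolded protein response genes, 10 had a lower effect, 13 adjusted over the list alone (camera adjusted p = 6.1e-06, and adjusted p = 0.254 with an estimated correlation), including Pdia4 at -1.82, Creld2 at -1.52 and Manf at -0.85. In NOD.scid alone, 4 of these genes rose with the transgene and 1 fell, the same adjusted over the list alone, and the list did not shift (camera adjusted p = 0.087). Of 7 erythrocyte genes, 4 had a lower effect, 6 adjusted over the list alone (camera adjusted p = 0.000218, and adjusted p = 0.147 with an estimated correlation), and of 16 neutrophil genes, 3, or 6 adjusted over the list alone (camera adjusted p = 0.0016, and adjusted p = 0.254 with an estimated correlation). The effect was higher for 3 of 28 matrix genes, and 3 adjusted over the list alone, with Dcn at 1.59 (camera adjusted p = 0.00466, and adjusted p = 0.254 with an estimated correlation). It was higher for 2 of 14 ribosomal genes, 4 adjusted over the list alone (camera adjusted p = 0.00163, and adjusted p = 0.27 with an estimated correlation). The oxidative stress list passed upward (camera adjusted p = 0.0473, and adjusted p = 0.254 with an estimated correlation), with 3 of 23 higher and 1 lower, or 5 and 2 adjusted over the list alone. Its mean was 0.170 and its median -0.018, with Mt1 at 2.12 and Prdx2 at -1.32. Ins2 had an interaction of -0.71 (limma adjusted p = 0.00548) on its brighter probe set and of 0.10, not past the threshold, on the other, and the interaction of Iapp (-0.63), Gcg (0.14) and Sst (-0.34) did not pass.

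Quantile normalization turned the split of 276 higher and 310 lower into 309 and 266, and centring array medians into 306 and 281, and leaving out single arrays turned it in 5 of 8 cases, so its balance is not settled. The count of 586 was 195 and 214 when BDC2.5/NOD replicate 1 or 2 was left out, 346 without NOD replicate 1, 197 with the BDC2.5/NOD arrays counted as 1 sample and 1042 with the actin control split as a term. Several list calls depended on 1 array: the matrix list had an adjusted p of 0.0652 without BDC2.5/NOD.scid replicate 2 and 0.0674 without NOD.scid replicate 2, and the oxidative stress list of 0.0701, 0.0921 and 0.149 without BDC2.5/NOD.scid replicate 2, NOD.scid replicate 2 and NOD replicate 1. Quantile normalization ended the call of the ribosomal list (adjusted p = 0.167) and of the oxidative stress list (0.0892).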

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

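The interaction test and the gene lists were fixed before the data were examined. Of the tests of an explanation in this part, all but the one on the neighbours of Prkdc were chosen only after the result was seen. Each result here was picked out because the effect of the transgene differed between NOD.scid and NOD by the interaction test, which 586 probe sets passed. The largest differences among named genes were 3.85 for Xist, 3.33 for the probe set annotated to Wdr92, 3.06 for Txnip, 2.95 for Pdk4 and 2.92 for Igkv6-23. In the other direction they were -2.62 for Pdxdc1, whose probe sets disagree, -2.44 for 1810009J06Rik, -2.20 for Reg3a, -2.18 for Car2 and -1.84 for Hemgn (-0.31 on a dimmer probe set). For Wdr92, Car2 and Hemgn, NOD.scid alone stood apart, with Wdr92 at 8.29 there and 11.25 to 11.9 in the other groups. By list, the median difference was 0.341 for macrophage, 0.415 for interferon gamma and MHC class I, 0.211 for MHC class II, 0.10 for matrix and 0.179 for ribosomal genes. It was -0.299 for neutrophil, -0.525 for erythrocyte, -0.496 for unfolded protein response and -0.018 for oxidative stress genes. All 9 list calls were lost with an estimated correlation. The sex of the animals is not given in the sources used here, and Xist differed within the NOD pair (7.26 and 4.60), so its value describes these pools. It lost its call in 9 alternative settings, as with a robust variance prior (adjusted p = 0.333), and was 2.52 (adjusted p = 0.0513) without NOD replicate 1. The Y-linked gene Eif2s3y was at 0.66 between NOD.scid and NOD (limma adjusted p = 0.0316). With the transgene in NOD.scid it was at -0.68 (limma adjusted p = 0.0119). Its group means were dim, below the median of all probe sets (4.27). The Y-linked Kdm5d and Uty, at 0.09 and 0.01 between NOD.scid and NOD, did not pass. A difference in sex between the pools stays open and cannot be separated from the comparisons.

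The interferon gamma, MHC and macrophage genes rose as lists with the transgene in NOD.scid and not in NOD, although with the actin control split as a term the interferon gamma list passed in NOD too (camera adjusted p = 0.0337, median 0.135), and the macrophage call in NOD.scid was lost with an estimated correlation (adjusted p = 0.094). A difference between the arrays of high and low actin control does not account for the difference between backgrounds, since the median interaction over the 65 genes was 0.41 within the arrays of low actin control and 0.35 pooled. Lymphoid tissue in the BDC2.5/NOD.scid pools would bring T cell and lymph node transcripts, and the upper quartile of the 13 such genes brighter than the median of all probe sets was 0.15. Since 3 of 5 probe sets of the T cell receptor segments Trav9d-3 and Trbv1 rose (0.49, 0.83 and 0.58), as did Gzmb (0.46), and how far such tissue would raise the others is not known, this decides nothing. Lymphoid tissue and a stronger response to the transgenic T cells without other lymphocytes cannot be told apart. Both readings take the labels as right. An exchange of labels between BDC2.5/NOD.scid and BDC2.5/NOD, left open below, would place the rise in mice with other lymphocytes.

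Red cell and neutrophil genes were higher in NOD.scid than in NOD. An additive shift with the actin control does not account for this, since each group had 1 array of high and 1 of low actin control. The median over all 23 genes of both lists was 0.40 within the arrays of low and 0.43 within those of high actin control. Of these genes, 23 and 19 were higher. These are the parts of the pooled difference by which the lists were picked, so they are not separate evidence. Mature blood left in the tissue stays open, since only 1 of Mpo, Elane and Prtn3, genes of neutrophil precursors, passed. Spleen tissue in the pools was not tested and stays open too, because scid spleen lacks the B cells whose transcripts would mark it. Hemgn, of erythroid precursors, rose as well, by 1.99, but was at 0.36 and did not pass on a dimmer probe set. The proliferation list also shifted upward, a call lost with an estimated correlation (camera adjusted p = 0.122). Neither was part of the test of precursor genes. Blood formation in the tissue of NOD.scid and different clearing of blood from the organ cannot be told apart by these few values.

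The immunoglobulin probe sets that passed were higher in the arrays labelled BDC2.5/NOD.scid than in those labelled NOD.scid, though both carry the scid label. Of all 75 immunoglobulin and Jchain probe sets, 56 were higher by a median of 0.08 over all, and 2 passed, both annotated to Igkv6-23, so that one aberrant sequence stays open. An exchange of labels between the BDC2.5/NOD.scid arrays and the BDC2.5/NOD arrays was tested on 76 probe sets of genes neighbouring Prkdc, which can differ with the chromosome segment carried along with scid. Of these, 1 passed in the same direction in both scid comparisons, against 0.21 by chance, and 0 in opposite directions, at Pearson r = -0.0099. The 3 probe sets of the neighbour Pdxdc1 were among the 5 that passed without the transgene, and none of the 3 passed with it. NOD stood apart on each, at 5.16 against 6.99 to 7.46, 5.55 against 4.55 to 4.64, and 5.64 against 5.01 to 5.35. The other groups include BDC2.5/NOD, so this gene did not follow the scid label. The 2 immunoglobulin probe sets that passed also read higher in BDC2.5/NOD.scid than in BDC2.5/NOD, by 0.71 and 0.72. Against NOD, BDC2.5/NOD was at -1.72 on both. Exchanged labels would give that order. With 1 shared call the neighbours of Prkdc cannot decide, so exchanged labels and a low level of immunoglobulin transcripts in these animals cannot be told apart.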

How the results depend on the processing

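The fits with a term for the actin control, with the BDC2.5/NOD arrays counted as 1 sample and without the arrays of high actin control were chosen after seeing the data. No named gene changed direction. The median of the oxidative stress list in the interaction, -0.018, lay near 0 and turned under several settings, to 0.043 under quantile normalization, 0.146 without BDC2.5/NOD.scid replicate 2 and 0.062 with the actin control as a term, while camera put the list upward in each. Its call was lost under quantile normalization and with the actin control as a term (camera adjusted p = 0.0892 and 0.0641). The title number as a term also ended it (camera adjusted p = 0.0535). The balance of higher and lower calls turned for the transgene in NOD.scid without BDC2.5/NOD.scid replicate 2 (295 and 500 to 234 and 211) and for the interaction under quantile normalization (276 and 310 to 309 and 266) and several other settings. For the transgene in NOD, nearly even at 486 and 504, it turned under 4 settings. The counts for the transgene in NOD.scid, the transgene in NOD, scid without and with the transgene, and the interaction (795, 990, 292, 1037 and 586) stayed within 1.5 times under quantile normalization, median centring, the filter on dim probe sets, the other variance priors and the title number. With only the arrays of a comparison in the fit, the first 3 counts were 455, 1521 and 143. Array weights gave 1568 for the transgene in NOD, and an adjusted p under 0.10 gave 1662 there and 466 for scid without the transgene, since more pass a looser threshold.

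With each array left out in turn, where the lone array of a group is assumed to vary like the other groups, the counts ranged from 445 to 746, from 279 to 1139, from 71 to 352, from 329 to 1149 and from 195 to 491. The actin control as a term gave 1315, 1507, 739 and 1526 for the pairwise comparisons and 1042 for the interaction. In that fit 292 probe sets passed the threshold for the actin control term itself. Counting the BDC2.5/NOD arrays as 1 sample gave 278, 311 and 197 for the transgene in NOD, scid with the transgene and the interaction, where the spread of that pair is lost and its arm has 1 sample, so the reason for the drop was not isolated. It gave 159 for scid without the transgene, where that pair is in neither arm and gives only part of the residual spread. Without the 3 arrays of high actin control they were 1418, 2179, 1489, 2138 and 1621, where the residual spread comes from the BDC2.5/NOD pair alone. Elsewhere the cause was not tested.

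Of 106 values of named genes, 101 kept their direction and side of the threshold in every setting in which they were fitted. The others were Xist, Pip4k2c, Nucb2, Car3 and Adipoq. With only the arrays of a comparison 96 of the values were fitted, and with the filter on dim probe sets 103. Of 47 list calls, 4 held with a correlation estimated from the residuals. The others kept their direction, and the cause was not tested. With the other settings 41 to 47 of the calls held. The alternatives with floors on linear values were not run because the values are on a log scale. No paired analysis was possible because the titles share only the number 1, on 1 array per group, and link the other arrays by nothing. A term that set the numbered against the other arrays, which pairs no samples known to belong together, gave counts of 647, 762, 195, 826 and 411, and the deviations of the numbered arrays correlated between groups at -0.32 to 0.29. Signal near background limits the dim genes, and the median of all probe sets was 4.27.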

Other observations

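The test of fatty acid oxidation genes was planned before their values were seen, and its repeat in the transgene comparisons and the genes named here outside it were chosen after. Ech1 and Eci2, enzymes of fatty acid oxidation, had log2 fold changes of -1.05 and -1.03 with the transgene in NOD, where Hadh was at -0.67 and Etfb at -0.63. In BDC2.5/NOD.scid, Ech1 was 1.29 above BDC2.5/NOD, and Eci2 was higher too.

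Of 5 probe sets of the T cell receptor segments Trav9d-3 and Trbv1, 3 rose with the transgene in NOD.scid and none in NOD. The brightest for Trav9d-3 had 0.49 against -0.12 and that for Trbv1 had 0.58 against -0.26, with interactions of 0.61 and 0.84 that passed (adjusted p = 0.0234 and 0.0112). The other passing one, for Trav9d-3, had an interaction of 0.91, while another for each segment did not, with interactions of 0.03 and 0.13. Erdr1 read 9.31 in NOD and 7.62, 8.01 and 7.81 in NOD.scid, in BDC2.5/NOD and lastly in BDC2.5/NOD.scid, so that NOD stood apart from the other 3 groups on this probe set and not on a dimmer one (6.76 in NOD and 6.48 to 6.66 in the others).

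Since Pdk4 and Txnip were higher and Fasn lower in BDC2.5/NOD.scid than in BDC2.5/NOD, a shift towards fatty acid oxidation, as in fasting, was tested on 22 other genes of that pathway. Their median was 0.19, under the 0.2 set beforehand, with 19 higher and 3 lower, and 6 passed, all higher (camera p = 5.98e-07, or 0.00535 with an estimated correlation). With the transgene in NOD the median of the same genes was -0.16 and 8 fell (camera p = 1.85e-06, or 0.0063 with an estimated correlation), and in NOD.scid it was 0.09 with 1 up and 2 down past the threshold (0.0783, or 0.125), so more of the difference lay in BDC2.5/NOD. A fasting-like state of BDC2.5/NOD.scid stays open, since Pdk4 and Txnip rose there with the transgene, by 2.32 and 1.57. Feeding before tissue was taken is not given in the sources used here.

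Several lists passed in no comparison. The lowest camera adjusted p was 0.298 for B cell genes, 0.194 for NK cell, 0.0728 for dendritic cell, 0.693 for mast cell, 0.26 for lymph node stroma, 0.373 for endothelial, 0.126 for hepatocyte and 0.199 for intestine genes. The sex-linked list had 4 measured genes and was not tested. Whereas the actin control term went with 292 probe sets past the threshold, the number 1 in the titles went with none (0) over the 4 groups. The arrays of that number in NOD and NOD.scid both had a high actin control (9.35 and 9.55) and their deviations correlated at 0.29, whereas in BDC2.5/NOD.scid the other array had it (9.26).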
